A study of Mus musculus with 10 samples.

How the data were processed

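RNA-seq was performed on leukemia stem cells sorted from the bone marrow of mice with MLL-AF9-driven acute myeloid leukemia. Per the labels' protocols, total RNA was extracted with a miRNeasy kit, reverse-transcribed and amplified by Geo-seq, a method for very small cell numbers, and made into libraries with a TruePrep kit. No molecular identifiers are described, so reads from amplified copies of 1 molecule cannot be separated, and precision from depth covers counting error only. Strand is not described either, so reads of a gene and of an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, the tools were Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq and DESeq2 with the mm10 build, with no role or order given. The gene annotation and any filter the authors applied are not given in the sources used here.

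The deposited table holds a signal for 52171 genes in 10 libraries. Within a library, values were whole multiples of a single step, whatever the gene, so the authors' signal is a read count divided by 1 factor per library and is called normalized reads here. It is not CPM and not per gene length, although the table is named as FPKM. Dividing by the step gave whole reads within 0.01 for all values above 0 in 8 libraries and for at least 99.962% in the others. Of the 52171 genes, 39862 had a read in at least 1 library. Recovered totals were 20.8 to 30.1 M reads in the floxed control libraries and 24.6 to 39.1 M in the Nup214 heterozygous libraries.

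Libraries were grouped by the genotype in their labels, 5 per group, and all 10 entered every fit except those that leave libraries out. The test was limma 3.58.1 in R 4.3.3 with an intensity trend, on log2(normalized reads + 1), with group as the only term. Genes with a value of at least 1 in at least 5 libraries were tested, 22458 in all. Fold changes are on this log2(value + 1) scale, which understates changes of low genes, and calls required a Benjamini-Hochberg adjusted p under 0.05. The fixed design used this test for a normalized unit and a count test for raw counts. The unit found was a normalized one. Nup214 was also tested by an exact permutation test. The labels do not say whether libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which can be partly technical.

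The 38 gene lists were fixed before the data were examined, and each was compared with the other tested genes by camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks only whether a list's own genes move on balance, were run beside it. Named genes followed a rule also fixed before the data were examined. It took Nup214 and the 10 higher and 10 lower genes with the smallest adjusted p and a mean of at least 5 CPM in the higher group, without predicted or unnamed genes. It added a panel of 19 ferroptosis, iron and leukemia genes, and the 2 to 4 members with the smallest p of each list called or described. The CPM for this rule came from the recovered reads. Of the genes this rule takes, 3 are not reported here, and they stayed in all fits and list counts. Symbols were matched to the GENCODE annotation of the same mouse build, and 49806 of the 52171 were found there.

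The tests were checked on simulated counts with this comparison's means and library sizes, in 3 runs with 200 changed genes each among 22458. Limma called 4.98% of genes changed 1.5-fold, 56.2% of those changed 2-fold and 90.4% of those changed 4-fold, with 15 calls among 66684 unchanged genes. A 30-gene list changed 1.5-fold had an unadjusted camera p under 0.05 in 3 of 3 runs, as had 2 of 300 unchanged lists. Simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.917. These runs therefore do not show how often camera errs on the real lists. Small changes of single genes were mostly below detection.

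Alternatives planned earlier were quantile normalization, upper quartile scaling, no filter, a filter of 5 in 5 libraries, a pseudocount of 0.1, sample quality weights, a replicate block and leaving out each library. Alternatives added after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, TMM scaling, a mean of at least 100 normalized reads, and leaving out heterozygous libraries 1 and 2 together or 3, 4 and 5 together. The edgeR quasi-likelihood test called 1010 genes higher and 808 lower among 13242 tested, and DESeq2 called 1645 higher and 2064 lower. The closest pair of libraries within a group differed by a chi-square of 18.5 per degree of freedom, so none was treated as a repeat of another. Permutation tests, level summaries and plots used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.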

Results

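Gene expression was measured by RNA-seq in leukemia stem cells of mice with acute myeloid leukemia driven by MLL-AF9, a fusion oncogene that turns myeloid progenitors leukemic. Cells had been sorted from bone marrow as negative for lineage markers and Sca-1 and positive for c-Kit, CD16/32 and CD34. One group of 5 libraries came from Nup214fl/+ mice, which carry a floxed allele of the nucleoporin gene Nup214, and is called floxed control. The other 5 came from mice that also carried Tie2-Cre, a recombinase active in endothelial and blood cells, and are called Nup214 heterozygous. Recovered depth was 26.9 M reads ± 3.59 (SD, n = 5) in the controls and 34.2 M ± 6.23 (SD, n = 5) in the heterozygous libraries. Genes with at least 1 read numbered 28555 ± 1380 (SD, n = 5) and 23659 ± 2413 (SD, n = 5).

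The comparison asks how loss of 1 Nup214 allele alters gene expression in leukemia stem cells, in a series whose title links Nup214 to ferroptosis, an iron-dependent form of cell death. Only the heterozygous group carried Tie2-Cre, so an effect of Cre cannot be told apart from one of Nup214 loss. Each genotype was also on its own animals. Other differences between mice or leukemias therefore cannot be told apart from Nup214 loss either, for any gene or list below. Nup214 (ENSMUSG00000001855.15) encodes a cytoplasmic-side component of the nuclear pore and lies on chromosome 2 from 31974436 to 32053975 of mm10, on the plus strand. It averaged 906 normalized reads ± 69.8 (SD, n = 5) in controls and 484 ± 83.1 (SD, n = 5) in heterozygous libraries, 53.4% of the control level. The libraries ranged from 811 to 984 and from 376 to 602, so all 5 heterozygous libraries lay below every control. The log2 fold change was -0.92 with an SE of 0.130 and a limma adjusted p of 0.00144. A two-sided exact permutation test over the 252 assignments gave p = 0.00794, the smallest it can give.

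**Figure D1:**
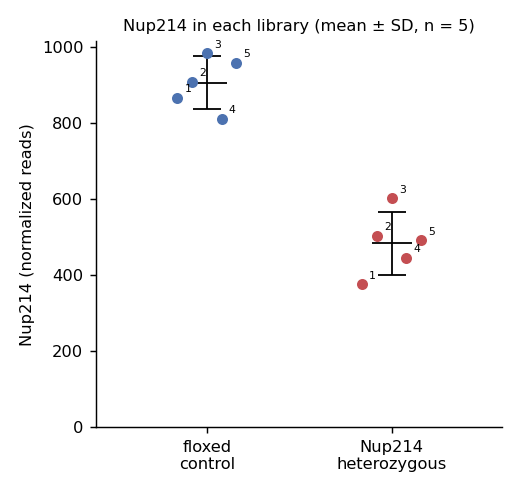
Nup214 in normalized reads for each library, numbered by replicate, with the mean and SD of each group (n = 5). The heterozygous libraries lie between 376 and 602 and the floxed controls between 811 and 984.

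In Nup214 heterozygous leukemia stem cells, 17 of 33 type I interferon response genes, 8 of 17 heat shock genes, 6 of 30 unfolded protein and integrated stress response genes and 11 of 34 autophagy and lysosome genes were called higher. Camera called these 4 lists higher, but with an estimated correlation only the unfolded protein list kept its call (adjusted p = 0.0268, against 0.167 for each of the others). Hmox1, which encodes the heme-degrading enzyme heme oxygenase, rose from 95.7 ± 20.8 to 506 ± 121 normalized reads (SD, n = 5 each), and Cd68, a lysosomal glycoprotein abundant in macrophages, from 661 ± 127 to 2513 ± 236. Genes that fell included the homeobox gene Hoxb2, from 304 ± 130 to 2.26 ± 4.62, and Tcf4, a transcription factor of plasmacytoid dendritic cells, from 628 ± 212 to 58.2 ± 27.8. Limma called 1122 genes higher and 1798 lower in heterozygous cells among 22458 tested, at a Benjamini-Hochberg adjusted p under 0.05. Without control library 1 these counts were 559 and 599, without control library 5, 653 and 762, and without control library 2, 727 and 1109. Without control library 3, 718 were higher, and without heterozygous library 5, 1014 were lower.

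The 10 genes leading the higher side, in order of adjusted p, were Xlr4a, Cd68, Hmox1, Cyp39a1, Nuak2, Mbnl2, Papss2, Sgip1, Irf9 and Pfkp, each above every control in 5 of 5 heterozygous libraries. Xlr4a, an X-linked gene with near-identical neighbors, averaged 0.397 ± 0.887 normalized reads in controls and 274 ± 76.6 in heterozygous libraries (SD, n = 5 each). Nuak2, an AMPK-related kinase, had a log2 fold change of 0.98 (SE 0.0913, adjusted p = 7.73e-05), and Mbnl2, a splicing regulator, one of 1.04 (SE 0.0989, adjusted p = 8.51e-05). Irf9, the DNA-binding subunit of the interferon-activated factor ISGF3, rose from 506 ± 53.7 to 1217 ± 159, and Pfkp, a phosphofructokinase of glycolysis, from 1309 ± 151 to 2942 ± 331. Log2 fold changes of the others were 2.12 for Cyp39a1, an oxysterol hydroxylase, and 1.37 for Sgip1. Papss2, which makes the sulfate donor of sulfation reactions, rose from 276 ± 48.8 to 834 ± 138.

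The 10 genes leading the lower side were Stfa1, Mir17hg, Cstdc5, Bcas1, Hoxb2, Tcf4, Pde4d, Ankrd63, Iftap and Cyb561a3, each below every control in 5 of 5 heterozygous libraries. Stfa1 and Cstdc5, stefin-type inhibitors of cysteine proteases, averaged 10967 ± 8474 and 8727 ± 6085 normalized reads in controls against 18.8 ± 13.4 and 9.07 ± 7.25 in heterozygous libraries (SD, n = 5 each). Stefin genes have near-identical copies, so how reads divide among them is uncertain. Mir17hg, the host transcript of an oncogenic microRNA cluster, fell from 397 ± 106 to 47.9 ± 6.79, and Pde4d, a cyclic AMP phosphodiesterase, from 1412 ± 425 to 270 ± 94.7. Bcas1 had a log2 fold change of -2.73, Ankrd63 of -2.16, Iftap of -1.22 and Cyb561a3 of -0.84.

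The direction of the calls depended on level. Among genes with means under 16 normalized reads, 48 were higher and 1219 lower, and the median log2 fold change was -0.82 below 4 and -0.77 from 4 to 16. Among the 3040 genes with means of 1024 and over, 474 were higher and 67 lower, with a median of 0.17. Long noncoding genes of the class lincRNA counted 12 higher and 141 lower of 928, and protein-coding genes 1051 higher and 1029 lower of 14857. The share of calls that were higher was 38.4% as fitted, 60.1% after quantile normalization, 29.4% after upper quartile scaling, 48.5% after TMM scaling, 51.3% with a filter of 5 in 5 libraries, 48.7% with a pseudocount of 0.1, 55.6% with edgeR on recovered reads and 75.5% among genes with means of at least 100. It was 42.5% with no filter, 39.9% with sample quality weights, 42.7% with a replicate block and 44.4% with DESeq2, and from 36.9% to 48.3% when 1 library was left out. The median log2 fold change of all genes was -0.19 as fitted and -0.02 after quantile normalization.

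**Figure D2:**
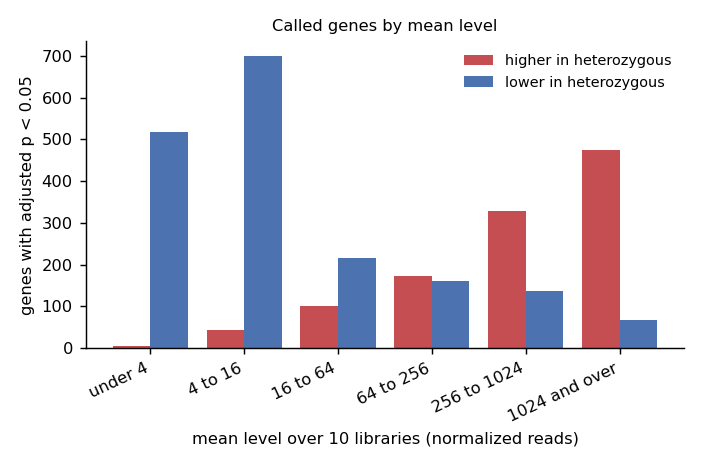
Genes called higher or lower in Nup214 heterozygous cells by limma, counted in 6 bins of mean normalized reads over the 10 libraries. Lower calls peak at 700 in the bin from 4 to 16, and higher calls at 474 in the bin of 1024 and over.

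The libraries also differed within the heterozygous group. The first principal component, with 39.7% of the variance, ran from -98.3 to -37.3 in the controls and from 6.46 to 132 in the heterozygous libraries. On the second, with 15.7%, heterozygous libraries 1 and 2 were at -84.2 and -85.7, and libraries 3, 4 and 5 at 47.8, 27.4 and 33.3. Hba-a1, an alpha-globin gene, read 1.91 and 31.1 in heterozygous libraries 1 and 2 and 801, 939 and 824 in libraries 3, 4 and 5. Retnlg, a product of mature neutrophils, read 6.68 and 12.3 in the first pair and 4218, 747 and 43005 in the other 3. With libraries 1 and 2 left out, 2095 genes were higher and 2707 lower, and with libraries 3, 4 and 5 left out, 1671 were higher and 1846 lower. Called in both of these fits were 557 higher and 595 lower genes.

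**Figure D3:**
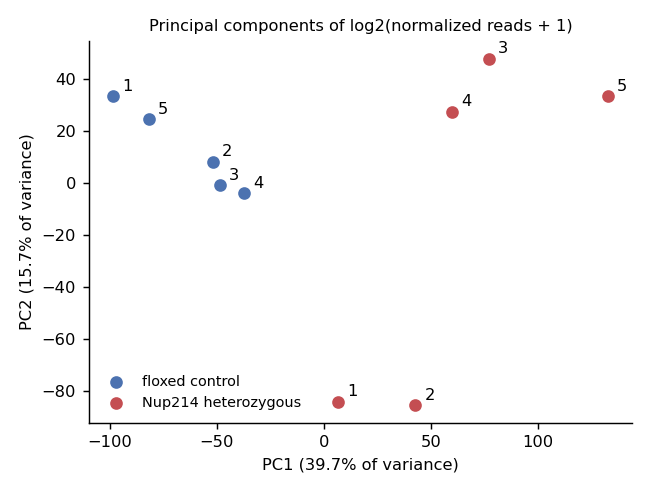
First and second principal components of log2(normalized reads + 1) for the 10 libraries, numbered by replicate. The heterozygous libraries lie at 6.46 and above on the first component, and libraries 1 and 2 lie at -84.2 and -85.7 on the second.

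Of 32 ferroptosis driver and marker genes tested, 4 were higher and 3 lower (5 and 5 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.130). It was called higher with no filter on low values and without heterozygous libraries 1 and 2 (adjusted p = 0.0217 and 0.0201). Without libraries 1 and 2, 11 members were higher and 5 lower, and without libraries 3, 4 and 5, 4 were higher and 7 lower. Hmox1, which is also in the iron and NRF2 lists, and Becn1, an autophagy initiator, rose, the latter by a log2 fold change of 0.45 (adjusted p = 0.0106). Gls2, a mitochondrial glutaminase, fell from 20.2 ± 6.04 to 2.80 ± 1.51 normalized reads (SD, n = 5 each), and the transferrin receptor gene Tfrc from 629 ± 53 to 385 ± 108 (adjusted p = 0.0149). After quantile normalization Becn1 lost its call (adjusted p = 0.185). Acsl4, which loads membranes with oxidizable fatty acids, averaged 231 ± 15.0 and 247 ± 75.7 and was not called (adjusted p = 0.882).

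Of 30 ferroptosis suppressor genes, 8 were higher and 2 lower (8 and 3 adjusted over the list alone), and camera called the list higher (adjusted p = 0.00697). Its median log2 fold change was 0.04, against -0.19 for all tested genes. The call was lost with an estimated correlation (adjusted p = 0.167), after quantile normalization (adjusted p = 0.406), with a filter of 5 in 5 libraries (adjusted p = 0.127) and among genes with means of at least 100 (adjusted p = 0.391). Gclm, the modifier subunit of the rate-limiting enzyme of glutathione synthesis, rose from 1480 ± 404 to 3913 ± 1233, and Mt1, a metallothionein, from 8179 ± 1682 to 16661 ± 3603 (SD, n = 5 each). Gch1, which starts tetrahydrobiopterin synthesis, had a log2 fold change of 0.99 (adjusted p = 0.00676). Aifm2, which encodes the ferroptosis suppressor FSP1, fell from 240 ± 32.6 to 127 ± 56.7 (adjusted p = 0.0257), a call lost without control library 2, 4 or 5 or heterozygous library 5 (adjusted p = 0.0571, 0.0509, 0.0503 and 0.0506). The glutathione peroxidase Gpx4 averaged 9545 ± 1110 and 12049 ± 2001 (adjusted p = 0.127), and the cystine transporter subunit Slc7a11 41.3 ± 8.33 and 49.8 ± 41 (adjusted p = 0.967), and neither was called.

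Iron and heme handling genes counted 6 higher and 2 lower of 30 (7 and 4 adjusted over the list alone), with no call for the list (camera adjusted p = 0.0678). The list was called higher with no filter and without control library 4 (camera adjusted p = 0.00967 and 0.0379). The ferritin chain genes Fth1 and Ftl1 rose by log2 fold changes of 1.05 (SE 0.239, adjusted p = 0.0165) and 0.82 (SE 0.189, adjusted p = 0.0174). Ferritin genes have many processed copies, which can share their reads, and Ftl1 lost its call after quantile normalization (adjusted p = 0.0893). Alas1, the first enzyme of heme synthesis, rose from 38999 ± 3235 to 87626 ± 13050 normalized reads (SD, n = 5 each), while Fech, the last enzyme of that pathway, fell from 2246 ± 354 to 1306 ± 430. Ncoa4, the receptor for ferritin degradation, averaged 17097 ± 907 and 15263 ± 1999 and was not called (adjusted p = 0.348).

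NRF2 and glutathione antioxidant genes counted 9 higher and 1 lower of 32 (11 and 2 adjusted over the list alone). The counts were 11 and 5 without heterozygous libraries 3, 4 and 5, and 12 and 2 without libraries 1 and 2. Camera called the list higher (adjusted p = 1.16e-05; adjusted p = 0.167 with an estimated correlation, 0.151 after quantile normalization and 0.129 among genes with means of at least 100). Nqo1, a quinone reductase, rose from 5.39 ± 2.39 to 29.0 ± 14.3, and Cat, which encodes catalase, from 1220 ± 81.3 to 1783 ± 259 (SD, n = 5 each). Nfe2l2, the gene of NRF2 itself, rose by a log2 fold change of 0.66 (SE 0.143, adjusted p = 0.0130). Without heterozygous libraries 3, 4 and 5 the calls of Nfe2l2 and Nqo1 ended (adjusted p = 0.0672 and 0.0718), and that of Cat ended after quantile normalization (adjusted p = 0.0520).

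**Figure D4:**
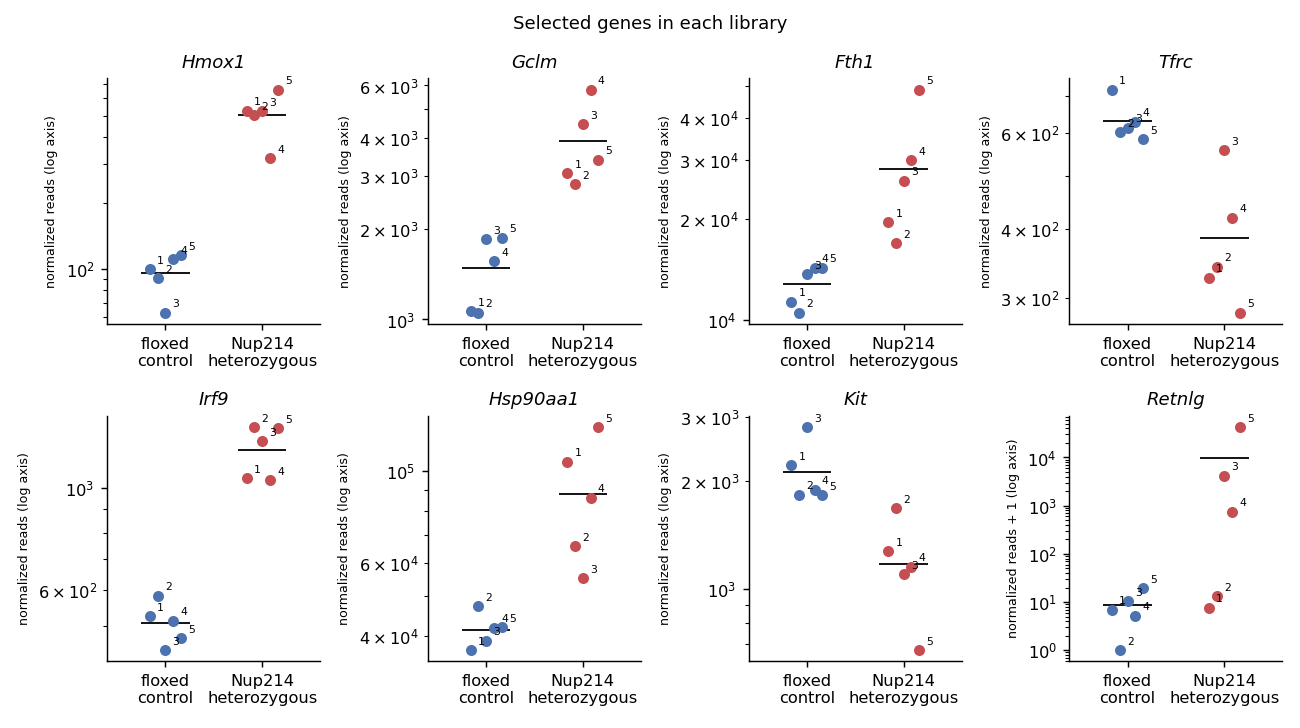
Normalized reads of 8 genes in each library on log axes, numbered by replicate, with group means as lines (1 was added to Retnlg, which has a value of 0). Hmox1 rises from a mean of 95.7 to 506 and Tfrc falls from 629 to 385, while Retnlg is high in heterozygous libraries 3, 4 and 5 and not in 1 and 2.

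Type I interferon response genes counted 17 higher and 0 lower of 33 (19 and 0 adjusted over the list alone). Besides Irf9, Oas1a, a sensor of double-stranded RNA, rose from 960 ± 111 to 2502 ± 642 normalized reads (SD, n = 5 each). Camera called the list (adjusted p = 4.12e-15), but not with an estimated correlation (adjusted p = 0.167). Without heterozygous libraries 3, 4 and 5, which had high erythroid and mature neutrophil markers, 10 members were higher and 1 lower, and without libraries 1 and 2, 25 were higher and 0 lower.

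Heat shock genes counted 8 higher and 0 lower of 17 (13 and 0 adjusted over the list alone). Ahsa1, a co-chaperone of HSP90, rose from 2441 ± 112 to 4794 ± 1046, Hsph1 from 422 ± 121 to 1333 ± 629, and Hsp90aa1 from 41470 ± 3829 to 87956 ± 29200 (SD, n = 5 each). The camera adjusted p was 4.97e-10, and the adjusted p with an estimated correlation was 0.167. Unfolded protein and integrated stress response genes counted 6 higher and 0 lower of 30 (12 and 0 adjusted over the list alone). Dnajb9, an endoplasmic reticulum chaperone, rose from 475 ± 50.2 to 1306 ± 321, and Ppp1r15a, a phosphatase subunit that reverses the stress response, from 82.3 ± 38.7 to 223 ± 108. The Ppp1r15a call was lost without control library 1, 2 or 3 or heterozygous library 5 (adjusted p = 0.0534, 0.0528, 0.0504 and 0.0502). This list had a camera adjusted p of 5.09e-07 and, alone among the 38, kept its call with an estimated correlation (adjusted p = 0.0268).

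Autophagy and lysosome genes counted 11 higher and 1 lower of 34 (16 and 2 adjusted over the list alone). The counts were 13 and 6 without heterozygous libraries 3, 4 and 5, and 18 and 1 without libraries 1 and 2. Ctsz, a lysosomal cathepsin, rose from 8553 ± 985 to 14694 ± 2244, Neu1, a sialidase, from 6956 ± 628 to 12073 ± 2164, and Hexa, a hexosaminidase subunit, from 15978 ± 1552 to 27222 ± 3808 (SD, n = 5 each). Camera gave an adjusted p of 4.21e-09, and an adjusted p of 0.167 with an estimated correlation. Glycolysis genes counted 4 higher of 22 (5 adjusted over the list alone), Pfkp and the hexokinase gene Hk3 (log2 fold change 0.90, adjusted p = 0.00658) among them. Hypoxia response genes counted 3 higher of 19 (3 adjusted over the list alone), led by Egln3 and Ndrg1 at log2 fold changes of 1.42 and 1.58. For these 2 lists the camera adjusted p was 0.00108 and 0.00681, and with an estimated correlation the adjusted p was 0.320 and 0.167. Quantile normalization ended both calls (adjusted p = 0.90 and 0.496) and left the glycolysis median below that of all genes. Without heterozygous libraries 3, 4 and 5, 2 glycolysis genes were higher and 4 lower, and the list was not called (adjusted p = 0.485).

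Markers of myeloid maturation did not move as 1 group. Monocyte and macrophage markers counted 7 higher and 0 lower of 23 (7 and 0 adjusted over the list alone), with Cd68 and the complement gene C1qc (45.2 ± 23.8 to 161 ± 74.2) as examples (camera adjusted p = 2.64e-06; adjusted p = 0.228 with an estimated correlation). The mean log2 level of this list was 6.43 to 7.34 in controls, 7.28 and 7.26 in heterozygous libraries 1 and 2, and 8.09, 8.10 and 8.53 in libraries 3, 4 and 5. Without libraries 1 and 2, 11 members were higher and 1 lower, and without libraries 3, 4 and 5, 4 were higher and 1 lower. Mature neutrophil markers counted 1 higher and 0 lower of 23 (1 and 0 adjusted over the list alone), the receptor gene Csf3r at 3426 ± 357 and 6426 ± 2115 (SD, n = 5 each). Camera called that list higher (adjusted p = 0.00452), but not with an estimated correlation (adjusted p = 0.603) nor after quantile normalization (adjusted p = 0.0968), nor without heterozygous library 3 or 5 (adjusted p = 0.0688 and 0.157). Without libraries 1 and 2, 20 neutrophil markers were higher and 1 lower, and without libraries 3, 4 and 5 none was higher and 15 were lower, which turned the direction of the list. Granulocyte-monocyte progenitor markers counted 6 higher and 2 lower of 22 (8 and 5 adjusted over the list alone, camera adjusted p = 0.0413, adjusted p = 0.455 with an estimated correlation). Of these, Prtn3, a granule protease, averaged 181880 ± 21400 and 301530 ± 38470, and its call was lost without control library 1, 2, 4 or 5 or heterozygous library 4 (adjusted p = 0.0659, 0.0794, 0.0561, 0.0743 and 0.0668). Cebpa averaged 137 ± 42.2 and 260 ± 63.9 and lost its call without control library 1, 2 or 5 (adjusted p = 0.0548, 0.0529 and 0.0604). The list itself lost its call without control library 1, 2 or 5 or heterozygous library 1 or 2 (adjusted p = 0.0623, 0.0530, 0.0817, 0.101 and 0.282), and after quantile normalization (adjusted p = 0.699). The azurophil granule gene Mpo averaged 970870 ± 143200 and 456780 ± 424200 (adjusted p = 0.0611) and Elane 873230 ± 65580 and 1107400 ± 137300 (adjusted p = 0.411), and neither was called.

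Hematopoietic stem and early progenitor markers counted 2 higher and 6 lower of 20 (3 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.931). Hoxb5, a stem cell homeobox gene, fell from 48.9 ± 34.9 to 0.191 ± 0.427, while Txnip, a thioredoxin inhibitor, rose from 1954 ± 119 to 3815 ± 641 (SD, n = 5 each). The stem cell factor receptor gene Kit, used in the sort, fell from 2113 ± 427 to 1174 ± 360 (adjusted p = 0.0184), with an adjusted p of 0.05 without control library 1. Cd34, also used in the sort, averaged 239 ± 103 and 176 ± 130 and was not called (adjusted p = 0.304). The MLL-AF9 leukemia program counted 1 higher and 1 lower of 28 (0 and 1 adjusted over the list alone), Lmo2 and Tcf4. The program was called higher (camera adjusted p = 0.0240; adjusted p = 0.286 with an estimated correlation), though not without heterozygous library 1, 2 or 3 (adjusted p = 0.0536, 0.0532 and 0.0517) nor after quantile normalization (adjusted p = 0.787). Lmo2 (log2 fold change 0.45, adjusted p = 0.0396) lost its call without control library 1, 2, 4 or 5 or heterozygous library 1, 2 or 4, with adjusted p from 0.0531 to 0.0981. Its core transcription factors were not called, with Hoxa9 at 4720 ± 246 and 5410 ± 1339 (adjusted p = 0.499), Meis1 at 3344 ± 662 and 4234 ± 170 (adjusted p = 0.0764) and Myb at 6658 ± 688 and 5834 ± 1872 (adjusted p = 0.407).

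Among markers of other cell types, erythroid genes counted 2 higher and 0 lower of 16 (2 and 0 adjusted over the list alone, camera adjusted p = 0.00525, adjusted p = 0.419 with an estimated correlation). Both, Hbb-bt and Hba-a1, are globin genes with near-identical neighbors, and without heterozygous libraries 3, 4 and 5 neither was called. Leaving out any 1 control or heterozygous library 3, 4 or 5 also ended the Hba-a1 call (adjusted p from 0.0548 to 0.0777). The Hbb-bt call ended without control library 1, 2, 3 or 5 or heterozygous library 3, 4 or 5 (adjusted p from 0.0559 to 0.0658). B cell markers counted 2 higher and 1 lower of 18 (3 and 1 adjusted over the list alone, camera adjusted p = 0.0260, adjusted p = 0.455 with an estimated correlation). Ighm, the immunoglobulin mu heavy chain, averaged 4185 ± 772 and 18308 ± 9906, and Cd79b, a B cell receptor subunit, 1125 ± 125 and 645 ± 187 (SD, n = 5 each). The B cell list lost its call without control library 3 or heterozygous library 3 or 5 (adjusted p = 0.0923, 0.109 and 0.0522), and after TMM scaling (adjusted p = 0.0518). Camera did not call the remaining marker lists with all 10 libraries. Fry called T and NK cell markers and endothelial and stromal markers lower (adjusted p = 0.0368 and 0.0168). Their median log2 fold changes were -0.40 and -0.32, against -0.82 and -0.77 for all genes under 4 and from 4 to 16 normalized reads. Fry does not compare a list with other genes, so these calls cannot be told apart from the general fall of low genes. Without heterozygous libraries 3, 4 and 5 camera called megakaryocyte and platelet markers lower (adjusted p = 0.0182). Dendritic cell and MHC class II genes counted 3 higher and 3 lower of 17 (5 and 4 adjusted over the list alone, camera adjusted p = 0.931), T and NK cell markers 0 and 2 of 14 (0 and 2, adjusted p = 0.317), and megakaryocyte and platelet markers 0 and 3 of 13 (0 and 3, adjusted p = 0.262). Endothelial and stromal markers counted 0 and 2 of 16 (0 and 2, adjusted p = 0.455), and mast cell, basophil and eosinophil markers 0 and 0 of 12 (0 and 0, adjusted p = 0.551). Examples were Runx2 at 841 ± 96.2 and 564 ± 74.2, the T cell gene Cd5 at 30.3 ± 12.9 and 5.90 ± 4.76, the platelet receptor gene Gp1bb at 58.8 ± 31 and 6.73 ± 4.71 and the endothelial gene Egfl7 at 95.7 ± 13.6 and 29.8 ± 6.88.

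G1/S and DNA replication genes counted 8 higher and 0 lower of 32 (8 and 0 adjusted over the list alone, camera adjusted p = 4.59e-06, adjusted p = 0.228 with an estimated correlation). Pcna, the sliding clamp of DNA polymerases, rose from 8988 ± 512 to 12734 ± 1351 (SD, n = 5 each), a call lost after quantile normalization (adjusted p = 0.135), as was that of the list (adjusted p = 0.699). G2/M and mitosis genes counted 1 higher and 0 lower of 30 (0 and 0 adjusted over the list alone, camera adjusted p = 0.0456, adjusted p = 0.670 with an estimated correlation), and the list was called lower after quantile normalization (adjusted p = 0.0130). Its call was also lost without control library 1, 3 or 5 or heterozygous library 2 or 4 (adjusted p = 0.0509, 0.0548, 0.211, 0.502 and 0.358). DNA damage repair genes counted 2 higher and 1 lower of 36 (2 and 1 adjusted over the list alone, camera adjusted p = 0.00415, adjusted p = 0.286 with an estimated correlation), with Nbn at a log2 fold change of 0.59 and the helicase gene Blm at -0.50, the latter lost without control library 1 (adjusted p = 0.0586). Quantile normalization ended the call of this list (adjusted p = 0.537). Of 25 replication-dependent histone symbols listed, 5 were in the table, all linker H1 genes, so core histones were not measured under this list. The list counted 1 higher of 5 (1 adjusted over the list alone, camera adjusted p = 0.0241, adjusted p = 0.286 with an estimated correlation), H1f2 at 641 ± 216 and 1123 ± 283. The H1f2 call ended without control library 1, 2 or 3 or heterozygous library 3 or 5 (adjusted p from 0.0596 to 0.0830), and that of the list without control library 2 or heterozygous library 1 or 2 (adjusted p = 0.0530, 0.0687 and 0.0535) and after quantile normalization (adjusted p = 0.0877).

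p53 target genes counted 2 higher and 0 lower of 30 (2 and 0 adjusted over the list alone, camera adjusted p = 7.4e-04, adjusted p = 0.320 with an estimated correlation), and BCL2 family and caspase genes 4 higher and 2 lower of 31 (5 and 3, adjusted p = 0.0172, adjusted p = 0.286 with an estimated correlation and 0.427 after quantile normalization). The mean log2 level of the p53 list was 6.59 to 6.86 in controls, 6.60 and 6.43 in heterozygous libraries 1 and 2, and 7.43, 7.22 and 7.34 in libraries 3, 4 and 5. Without libraries 1 and 2, 14 p53 targets were higher and 0 lower, and without libraries 3, 4 and 5, 0 were higher and 1 lower. In the latter fit neither the p53 list nor the BCL2 list was called (adjusted p = 0.81 and 0.352). The cell death gene Bax, in both, rose from 937 ± 55.1 to 1403 ± 193, and Casp1, an inflammatory caspase, from 416 ± 77.1 to 666 ± 65.0 (SD, n = 5 each). Ccng1 rose by a log2 fold change of 0.65 (adjusted p = 0.0346), which was lost without control library 1, 3, 4 or 5 or heterozygous library 3, 4 or 5 (adjusted p from 0.0541 to 0.0761). Trp53 averaged 5105 ± 690 and 5636 ± 1559 (adjusted p = 0.732) and Cdkn1a 166 ± 38.0 and 522 ± 404 (adjusted p = 0.0713), and neither was called. Immediate early genes counted 6 higher and 0 lower of 22 (7 and 0 adjusted over the list alone, camera adjusted p = 2.73e-06, adjusted p = 0.286 with an estimated correlation), and NF-kB and inflammatory genes 2 and 0 of 29 (2 and 0, adjusted p = 4.66e-05, adjusted p = 0.228 with an estimated correlation). Nfkbia, the NF-kB inhibitor, is in both and rose from 2595 ± 247 to 5565 ± 1894. Ier3 had a log2 fold change of 1.40 and the prostaglandin synthase gene Ptgs2 one of 3.36, both lost without control library 1 (adjusted p = 0.0573 and 0.0521). Without heterozygous libraries 3, 4 and 5, 1 immediate early gene was higher and 1 lower, and 3 NF-kB genes were higher and 3 lower, and neither list was called (adjusted p = 0.134 and 0.172). Without libraries 1 and 2, 13 and 10 members were higher and 0 lower.

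Ribosomal protein genes had 0 of 75 called (0 adjusted over the list alone; 63 were higher without heterozygous libraries 3, 4 and 5 and 0 without libraries 1 and 2), although camera called the list higher (adjusted p = 1.56e-11; adjusted p = 0.455 with an estimated correlation and 0.352 after quantile normalization). Rps9 averaged 37463 ± 6009 and 51096 ± 10250 and Rpl13 77315 ± 12620 and 106690 ± 19300 (SD, n = 5 each), and reads can be shared with their many processed pseudogenes. Mitochondrially encoded mRNAs counted 4 higher and 0 lower of 13 (8 and 0 adjusted over the list alone, camera adjusted p = 4.59e-06, adjusted p = 0.286 with an estimated correlation). Their mean log2 level was 14.75 and 14.85 in heterozygous libraries 1 and 2, 13.82, 14.38 and 14.28 in libraries 3, 4 and 5, and 13.74 to 13.99 in controls. Of the 13, 1 was higher without libraries 1 and 2, and 12 were without libraries 3, 4 and 5. Of these genes, mt-Nd2 averaged 2752 ± 389 and 4763 ± 1313 and mt-Nd3 852 ± 219 and 1389 ± 313, and both lost their calls after quantile normalization (adjusted p = 0.0838 and 0.0898) and without control library 1 (adjusted p = 0.0510 and 0.0790). The mt-Nd3 call also ended without control library 4 or 5 or heterozygous library 2 or 4 (adjusted p from 0.0527 to 0.0731). Nuclear-encoded oxidative phosphorylation genes counted 2 and 0 of 48 (1 and 0 adjusted over the list alone, camera adjusted p = 2.09e-05, adjusted p = 0.497 with an estimated correlation), with Ndufa5 at a log2 fold change of 0.68 and Sdhb at 0.41. The Sdhb call ended without control library 1, 2, 3 or 5 or heterozygous library 2, 4 or 5 (adjusted p from 0.0590 to 0.105). MYC-regulated ribosome biogenesis genes had 0 of 30 called (0 adjusted over the list alone, camera adjusted p = 0.721). Their mean log2 level was 10.33 and 10.34 in heterozygous libraries 1 and 2, 9.95, 9.92 and 9.74 in libraries 3, 4 and 5, and 10.01 to 10.23 in controls. Without libraries 3, 4 and 5, 11 members were higher and 0 lower and the list was called higher (adjusted p = 3.46e-05). Without libraries 1 and 2, 0 were higher and 5 lower and it was called lower (adjusted p = 0.0199), as it was after quantile normalization (adjusted p = 0.0109). After quantile normalization the oxidative phosphorylation list changed sign without a call (adjusted p = 0.0968), and 8 of its members were higher without libraries 3, 4 and 5 and 2 without libraries 1 and 2. Cholesterol biosynthesis genes counted 0 higher and 3 lower of 25 (0 and 3 adjusted over the list alone, camera adjusted p = 0.523), and the list was called lower among genes with means of at least 100 and after quantile normalization (adjusted p = 0.00702 and 0.0127). Pmvk, a mevalonate pathway kinase, fell from 304 ± 27.0 to 197 ± 20.1, and Srebf2, the pathway's transcriptional activator, from 1157 ± 279 to 709 ± 105, the latter lost without control library 1 (adjusted p = 0.0532). Fatty acid synthesis and desaturation genes counted 3 and 1 of 30 (4 and 4 adjusted over the list alone, camera adjusted p = 0.429), with the elongase gene Elovl1 at a log2 fold change of 0.51, a call lost without control library 5 (adjusted p = 0.0519).

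Nucleoporins other than Nup214 counted 0 higher and 2 lower of 27 (2 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.372). Pom121 averaged 355 ± 39.5 and 246 ± 32.4 and Nup155 704 ± 72.5 and 522 ± 70.8 (SD, n = 5 each), and after TMM scaling 3 members were higher and neither of these was called. The Pom121 call also ended without control library 1, 2 or 3 or heterozygous library 4 or 5 (adjusted p from 0.0513 to 0.0664), and the Nup155 call without any 1 library other than control 4 and heterozygous 4 (adjusted p from 0.0503 to 0.0874). Nuclear transport receptors and mRNA export factors counted 1 higher and 1 lower of 29 (0 and 1 adjusted over the list alone, camera adjusted p = 0.277). Xpo5, the exportin of microRNA precursors, fell from 1724 ± 119 to 1067 ± 111 (adjusted p = 0.00212), and Nxf1, the main mRNA export receptor, averaged 2559 ± 154 and 3274 ± 379 (adjusted p = 0.0473), a call lost without any 1 library other than heterozygous library 3 (adjusted p from 0.0523 to 0.101). Both lists were called lower after quantile normalization (adjusted p = 0.0211 and 0.0323). With heterozygous libraries 3, 4 and 5 left out, 6 nucleoporins were higher and 6 lower, and 6 transport factors were higher and 4 lower. With libraries 1 and 2 left out, these counts were 0 and 1, and 2 and 1.

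Some lists had a median, mean and camera direction of different sign, since camera compares a list with the other genes. All tested genes had a median log2 fold change of -0.19, and those under 4 normalized reads one of -0.82. A list can thus be called higher with a median near 0, as were ferroptosis suppressors (0.04), G2/M (0.07) and DNA repair genes (0.07). Camera called 25 lists higher and 0 lower as fitted, but 7 higher and 1 lower among genes with means of at least 100. Mean and median log2 fold changes were -0.02 and 0.06 for BCL2 family and caspase genes and -0.06 and 0.30 for granulocyte-monocyte progenitor markers, both called higher. Among lists without a call that camera placed on the higher side, both values were negative for dendritic cell and MHC class II, fatty acid and MYC ribosome biogenesis genes. The mean was negative and the median positive for nucleoporins and transport factors, and the reverse held for ferroptosis drivers.

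Among genes with means of at least 100, list calls also ended for p53 targets (adjusted p = 0.365), BCL2 family and caspase genes (0.223), the MLL-AF9 program (0.987), granulocyte-monocyte progenitor (0.80), mature neutrophil (0.775) and monocyte and macrophage markers (0.129). There they also ended for G1/S (0.0763), G2/M (0.775), oxidative phosphorylation (0.310), glycolysis (0.566), hypoxia (0.566), NF-kB (0.391) and DNA repair genes (0.943). With a filter of 5 in 5 libraries the calls ended for BCL2 (0.127), MLL-AF9 (0.370), granulocyte-monocyte progenitor (0.254), mature neutrophil (0.171), erythroid (0.276), B cell (0.464), G2/M (0.376), histone (0.127), hypoxia (0.113) and DNA repair lists (0.113). Leaving out heterozygous libraries 1 and 2 together ended those of the MLL-AF9 (0.175), granulocyte-monocyte progenitor (0.845), G2/M (0.387) and histone lists (0.253). Without libraries 3, 4 and 5 those of the erythroid (0.985) and B cell lists (0.856) ended. With edgeR the calls ended for ferroptosis suppressors (0.0998), p53 targets (0.112), BCL2 (0.353), MLL-AF9 (0.832), granulocyte-monocyte progenitor (0.284), B cell (0.0571), G2/M (0.806), histone (0.193), oxidative phosphorylation (0.0892), hypoxia (0.132) and DNA repair lists (0.372). The G2/M call also ended after upper quartile scaling (0.124) and with a pseudocount of 0.1 (0.0528), and the granulocyte-monocyte progenitor call with sample quality weights (0.0752) and with a replicate block (0.0674). Fry called higher the lists of ferroptosis suppressors (0.0262), NRF2 (0.0105), hypoxia (0.00208), unfolded protein (0.00208), heat shock (0.0152), interferon (0.0152), autophagy (0.0104), G1/S (0.0368) and monocyte and macrophage genes (0.0368).

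For lists not described this way above, the members higher and lower were as follows, first without heterozygous libraries 1 and 2 and then without libraries 3, 4 and 5. They were 10 and 0, then 12 and 0 for heat shock genes and 7 and 1, then 11 and 2 for unfolded protein genes. They were 8 and 4, then 7 and 2 for ferroptosis suppressors and 8 and 5, then 5 and 3 for iron genes. Leukemia and progenitor lists gave 1 and 2, then 6 and 3 for the MLL-AF9 program, 5 and 6, then 7 and 1 for granulocyte-monocyte progenitor markers, and 5 and 7, then 3 and 5 for stem and early progenitor markers. Other cell types gave 7 and 0, then 0 and 0 for erythroid and 6 and 1, then 1 and 1 for B cell markers. There were 4 and 4, then 3 and 2 for dendritic cell, and 0 and 2, then 0 and 3 for T and NK cell markers. They gave 2 and 3, then 0 and 2 for megakaryocyte, 4 and 2, then 1 and 0 for mast cell, and 1 and 3, then 1 and 2 for endothelial markers. Growth lists gave 8 and 2, then 6 and 0 for G1/S and 1 and 1, then 2 and 2 for G2/M genes. They gave 3 and 2, then 6 and 2 for DNA repair, and 1 and 0, then 2 and 0 for histone genes. The rest were 7 and 4, then 3 and 4 for BCL2 family and 3 and 1, then 4 and 2 for hypoxia genes, followed by 0 and 2, then 1 and 4 for cholesterol, and 5 and 6, then 2 and 2 for fatty acid genes. Glycolysis genes counted 6 and 0 without libraries 1 and 2.

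Other named genes changed their calls with the libraries used. Without heterozygous libraries 3, 4 and 5, the calls of Aifm2 (adjusted p = 0.176), Fech (0.10), C1qc (0.0903), Ppp1r15a (0.0942), Csf3r (0.0709), Kit (0.0521) and Bax (0.0502) ended, while Hoxa9 (log2 fold change 0.51), Trp53 (0.47) and Gpx4 (0.42) were called higher. Without heterozygous libraries 1 and 2, Mpo (-2.56), Cd34 (-1.14) and Myb (-0.56) were called lower and Cdkn1a (2.11) higher. Quantile normalization also ended the calls of Csf3r, Prtn3, Ccng1, H1f2, Elovl1, Sdhb, Lmo2 and Nxf1, with adjusted p from 0.0750 for Csf3r to 0.398 for Nxf1.

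**Figure D5:**
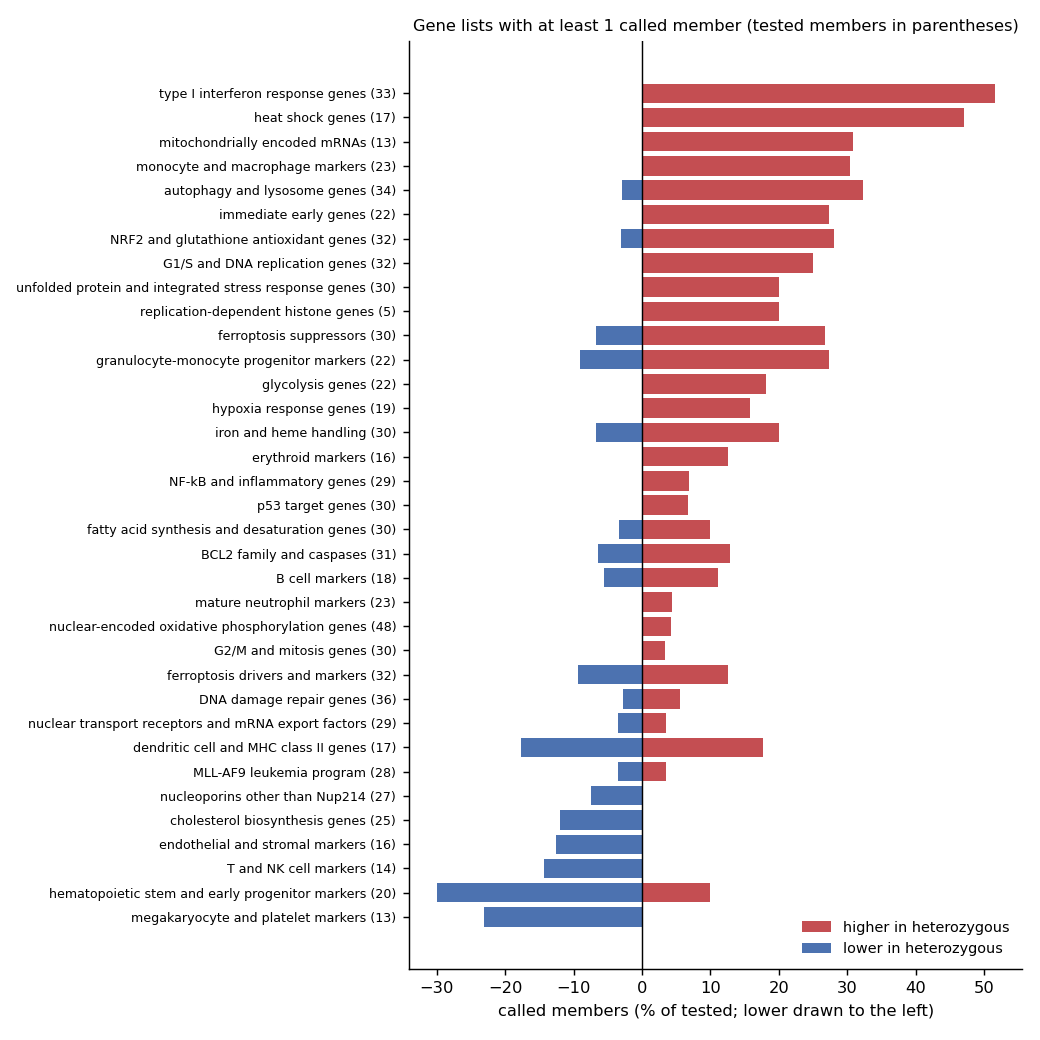
Share of the tested members of each list called higher (right) or lower (left) in Nup214 heterozygous cells by limma, for the lists with at least 1 called member. Higher are 17 of 33 type I interferon response genes and 8 of 17 heat shock genes, and lower are 6 of 20 hematopoietic stem and early progenitor markers.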

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

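Tests of the 3 patterns below were chosen after the results were seen, apart from the counts over other splits of the libraries, whose rule was written earlier. The 10 libraries were split in 100 of the 126 possible ways into 5 and 5. The real split gave 1122 genes higher and 1798 lower, and no other drawn split gave more than 2 of either. For both counts 1 of 100 was thus as large, the smallest share that 100 splits can give. That argues against an accidental grouping only if the libraries are independent, which the labels do not state. For gene lists called by camera the real split gave 25 and was again the largest, 1 of 100, but the highest other split gave 22 and the median 13. The 20 drawn splits that exchanged 1 library of each group gave 10 to 22 lists (median 18), and the 79 that exchanged 2 gave 0 to 22 (median 11).

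Genes with means under 16 normalized reads were lower in the heterozygous libraries, 1219 against 48 higher. These libraries were not shallower, with 34.2 M reads on average against 26.9 M. A single factor per library moves all genes alike, but the highest level bin and the bin of 4 to 16 differed in median log2 fold change by 0.94, which argues against the scaling. Olfactory and vomeronasal receptor genes, taken as a measure of background although some have roles outside the nose, had 215 CPM ± 77.0 (SD, n = 5) in controls and 74.2 ± 22.3 in heterozygous libraries (two-sided exact permutation p = 0.00794, the smallest possible), and of 1406 such genes with reads 1314 had the higher mean in controls. These genes are themselves of low level on average, at 215 CPM for all together in controls. Their lower reads therefore cannot separate background from an effect on low transcripts. Background reads from outside mature mRNA in the controls are a candidate explanation and may account for part of the lower calls, while an effect of the genotype on low transcripts stays open and untested.

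Erythroid, mature neutrophil and some B cell markers were higher in heterozygous libraries 3, 4 and 5, although the sort took lineage-negative cells, with Hba-a1 at 801 to 939 normalized reads and Igkc at 3253 to 8149 against at most 14.9 and 320 in controls. The B cell gene Cd79b was lower there, 474 to 564 against 1014 to 1319, and the mean log2 level of T and NK cell markers was 2.09 to 2.51 against 2.56 to 3.05. That level was also low in heterozygous libraries 1 and 2, at 2.13 and 1.72. Genes of low level were lower in the heterozygous libraries in general, and T and NK cell markers are of low level. The genotype raising mature neutrophil markers alike in every library is argued against, as the mean log2 level of that list lay below every control in 2 of 5 heterozygous libraries (7.12 and 7.86 against 9.43 to 10.25), while its effect on the other markers stays open and untested. Mpo was low in these libraries, at log2 ratios to the control mean of -3.02, -2.24 and -2.40. The median ratio of the 28 MLL-AF9 program genes was 0.188, 0.088 and -0.073, with lower quartiles of -0.09, -0.27 and -0.44. Elane had ratios of 0.236, 0.512 and 0.497. These values argue against dilution, as the whole cause, by cells that lack these transcripts. Cells that express them need not lower them, so dilution by such cells stays open and untested. RNA or cells of erythroid and B lineages carried through the sort cannot be told apart from another state of these leukemias, which was not tested: both lists shared 3 of their 3 highest libraries, but 12 of the 38 lists had the same 3.

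Type I interferon response genes were higher in the heterozygous libraries. Libraries 3, 4 and 5 alone do not carry this, since 10 members were still higher with them left out. The mean log2 level of the list was 5.86 to 7.37 in heterozygous libraries and 5.50 to 5.77 in controls. It lay above every control in 5 of 5, as an effect of the Nup214 genotype would need. The list was singled out because it was higher in these same libraries, so this order is no separate support for such an effect. A difference between mice or leukemias other than Nup214 cannot be told apart from it, because each genotype is on its own animals and members move together between libraries (camera adjusted p = 0.167 with an estimated correlation). Nor can an effect of Tie2-Cre, which only the heterozygous group carried. An effect of losing 1 Nup214 allele on interferon signaling may therefore be followed up only as a hypothesis.

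In 16 of 356 groups of 5 libraries, 1 library lay far from the other 4. Chance alone gives about 1 in 20 for normally spread values, which genes of few reads do not have. Among controls, in normalized reads, Men1 was 661 in library 5 against 722 to 745 in the others. Fancl was 135 in control library 1 against 171 to 187, and Nfkbia 2173 there against 2627 to 2812. Xlr4a was 1.98 in control library 1 and 0 in the other controls, and Ctsz 10275 in control library 4 against 7964 to 8476. Heterozygous library 1 had Hoxb2 at 10.5 against 0 to 0.794, Hoxb5 at 0.954 against 0, Gp1bb at 0 against 5.72 to 12.7 and Pf4 at 0.954 against 4.09 to 6.15. In that library 0.954 is 1 read. Where the other 4 values are all 0, as for Hoxb5 and Xlr4a, any read is flagged, so these flags carry no weight. Heterozygous library 5 was low for Cebpa (151 against 257 to 307), Ppan (501 against 750 to 847), Runx2 (438 against 569 to 629) and Tnip1 (478 against 846 to 1026). Heterozygous library 4 was high for Becn1 (5473 against 4666 to 4849) and Sgip1 (18357 against 12346 to 13545), and heterozygous library 3 low for Nup93 (1225 against 1631 to 1827).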

How the results depend on the processing

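Nup214 stayed lower in every setting run, with log2 fold changes from -1.05 to -0.83. Of the values of named genes under the alternatives, 3442 kept their call or stayed without one, 373 lost and 137 gained a call. None reversed, which counts only changes of direction where either fit made a call. Changes of direction without a call in both fits were not counted. For lists these numbers were 725, 83 and 8, with 10 reversed by the same rule. The settings chosen after seeing the data were edgeR, DESeq2, TMM scaling, means of at least 100 and both joint leave-outs. For settings that moved a count by over 1.5 times, the cause was not tested. Some of these settings used fewer genes or libraries, and how far that moved the counts was not tested either. Quantile normalization gave 517 genes lower and 11 lists higher and 5 lower. Lower genes numbered 1119 with no filter, 1063 with a filter of 5 in 5 libraries (14 lists higher), 1028 with a pseudocount of 0.1, 808 with edgeR (13 lists higher) and 311 among genes with means of at least 100 (7 lists higher, 1 lower). Without heterozygous libraries 1 and 2, 2095 genes were higher and 2707 lower and 1 list lower, and without libraries 3, 4 and 5, 2 lists were lower. Camera with an estimated correlation called 1 list higher, and fry 9 higher and 2 lower. Leaving out 1 library gave 559 (without control 1) to 1313 (without heterozygous 1) genes higher, 599 to 2250 lower for the same libraries, 21 to 26 lists higher and 0 lower. Lower genes also fell by over 1.5 times without control 2 (1109), control 5 (762) or heterozygous 5 (1014), and higher genes without control 2 (727), 3 (718) or 5 (653).

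Reversed lists, as median log2 fold change minus that of all genes, were after quantile normalization nucleoporins (-0.125), transport factors (-0.0869), granulocyte-monocyte progenitor markers (0.0782), G2/M genes (-0.132), MYC ribosome biogenesis genes (-0.176) and oxidative phosphorylation genes (-0.0531). They were also the MLL-AF9 program (0.0609) and G2/M genes (-0.0185) among means of at least 100, MYC ribosome biogenesis genes (-0.0583) without heterozygous libraries 1 and 2, and mature neutrophil markers (-2.11) without 3, 4 and 5. Positive values among these reversed in camera's direction only, and the cause was not tested. Replicate numbers did not pair the libraries, with correlations of same-numbered deviations from -0.231 to 0.216 and the best match at the same number only for replicate 5. A replicate block gave 703 genes higher and 945 lower. EdgeR with relative log expression scaling, planned for raw counts, was not run, though DESeq2 scaled by such median ratios. Depth of 20.8 to 39.1 M reads leaves genes of few reads the least certain.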

Other observations

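The gene groups in this paragraph and the next were chosen after their values were seen. MHC class I and antigen processing genes, which present peptides to T cells, counted 11 higher and 0 lower of 18, with a median log2 fold change of 1.11. B2m, the light chain of class I molecules, rose from 51545 ± 6504 to 132990 ± 25980 normalized reads (SD, n = 5 each), and Tap1, a peptide transporter, from 1082 ± 129 to 2253 ± 212. Psmb9, an immunoproteasome subunit, had a log2 fold change of 0.96, and all 3 genes lay above every control in 5 of 5 heterozygous libraries. H2-Q6 and H2-Q7 averaged 145 ± 59.9 and 222 ± 87.6 in controls and 3121 ± 2181 and 5218 ± 4014 in heterozygous libraries, and their similar sequences leave the division of reads between them uncertain.

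Of the Hoxb genes 4 were tested and 3 were lower, Hoxb1, Hoxb2 and Hoxb5. Of 5 stefin and Cstdc genes tested all 5 were lower. Of 5 Xlr genes tested 3 were higher, Xlr4a, Xlr4b and Xlr4c, at log2 fold changes of 7.74, 3.31 and 6.33, and these copies also share sequence. Ltf, a secondary granule gene, read 131 and 186 in heterozygous libraries 1 and 2, 108700, 45346 and 286970 in libraries 3, 4 and 5, and 593 to 4057 in controls. The Y-linked gene Ddx3y read 36.5, 30.1 and 64.6 in heterozygous libraries 3, 4 and 5 and at most 6.26 in the others, and the Y-linked gene Eif2s3y 44.4, 49.0 and 96.9 and at most 4.69. The Y-linked genes Kdm5d and Uty did not share this pattern against the controls, at 7.69 to 9.52 and 10.3 to 27.7 in these 3 libraries and 5.22 to 16.9 and 6.56 to 25.8 in controls. Within the heterozygous group they did, as libraries 1 and 2 had Kdm5d at 1.91 and 0.817 and Uty at 0 and 3.27. The labels give neither the sex nor the animal of a library.

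The chromosome test below was chosen after the results were seen, and the rules of the other tests in this paragraph were written earlier. The rule on NRF2 and BACH1 targets follows up the rise of Hmox1, Gclm and Nqo1 in these same libraries. Gain or loss of a whole chromosome in 1 group is argued against, since the largest median log2 difference of any chromosome in any library was 0.107 in size, for chromosome 14 in heterozygous library 3. Genes within 10 Mb of Nup214 were called in 39 of 324 cases (12%) and others in 2793 of 21366 (13.1%), which gave no excess of calls near the locus (one-sided Fisher's exact p = 0.732). Both groups carried the floxed allele, so DNA linked to it is shared, and this test could not show genes carried along with it. Of 12 further NRF2 and BACH1 target genes outside the fixed lists, 11 were tested. Their median log2 fold change of 0.27 lay at percentile 99.2 of 10000 random lists matched on mean level. Genes in those lists were drawn independently, so the percentile leaves out targets moving together and the spread between libraries. A wider raising of such targets therefore stays a hypothesis. Only 1 of them, Blvra (log2 fold change 0.68, limma adjusted p = 0.00605), was called, and Osgin1 and Pir both had log2 fold changes of -0.36.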
